A study of Mus musculus with 12 samples.

How the data were processed

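Whole lung from mice was profiled by RNA sequencing. Per the labels' protocols, total RNA was extracted with an RNeasy kit, messenger RNA was enriched with oligo-dT beads, and libraries were made with a NEBNext Ultra RNA kit, with no statement on strand. Mice carried Cc10-Cre alone, or Cc10-Cre with both alleles of *Rhoa* floxed. Each genotype received PBS or a treatment labelled CRE. The labels do not spell CRE out, and it is kept as a label here, distinct from the Cre recombinase. The 4 groups are called WT_PBS, CKO_PBS, WT_CRE and CKO_CRE, with 3 libraries each and a single batch number in the labels.

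The values used were read counts per gene as deposited, in 1 table of 54532 Ensembl gene identifiers by 12 libraries, and every column was used. Per the submitters' processing notes, fastp, STAR and the mouse build mm10 were used, with no versions. The counting tool, its strand setting, its handling of reads that match several places and its gene annotation are not given in the sources used here. Library totals ran from 16250674 to 21559210 counts. Symbols and positions came from GENCODE M21 on GRCm38 (mm10), which matched 54409 identifiers. The other 123 held at most 0.042% of any library's counts and stayed in the fit. 22229 genes had no count in any library.

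Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors, genes kept by filterByExpr, a mean per group over all 12 libraries, and the quasi-likelihood F test. The Benjamini-Hochberg method adjusted p over the 17473 tested genes, and a gene was called at an adjusted p below 0.05. The biological coefficient of variation was 17.4%. All adjusted p-values of genes are from this test unless another tool is named. Log2 fold changes are given ± SE and counts scaled to library size (CPM) as mean ± SD over 3 libraries. Contrasts were CRE against PBS in each genotype, CKO against WT under each treatment, and the difference between the CRE responses of the genotypes (the interaction).

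Before the data were examined, 39 gene lists for lung cell types, immune responses and pathways were fixed, as were the groups, the tests, the processing alternatives and the rule for naming genes. Lists were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, at least 5 tested members), with p adjusted over the lists of a contrast, and again with an estimated correlation. 36 lists were counted. Lists of sex-linked and mitochondrially encoded genes served as checks only, and a thymus precursor list had too few tested members. Members past the threshold were counted over all genes and adjusted over the list alone. Several lists share members, and whole lung holds every cell type they name.

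Named genes were those called, with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups compared, a separation that chance gives in 10% of comparisons of 3 with 3. Of these, the 8 with the largest rise and the 8 with the largest fall were eligible, leaving out predicted symbols, pseudogenes, ribosomal protein genes, sex-linked genes and antigen receptor segments. Up to 2 rising and 2 falling called members of each list were added, and a fixed set around *Rhoa*, *Scgb1a1*, type 2 cytokines, *Muc5ac*, *Ccl11*, *Chil3*, *C1qa* and *Cldn18*. For the interaction the 8 called genes with the smallest p were named. The text describes a part of these, and a gene eligible under the rule is not reported here. Where all libraries of a group had 0 counts, the fold is a bound against a floor of 3 counts per library. Such floors cover counting error only.

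Alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom with library quality weights, no low-count filter, the replicate number as a block, only the groups compared, a 2-fold threshold, and each library left out in turn. After seeing the data, the sex of each mouse, read from Y-linked counts, was added as a covariate, and the genotype comparisons were repeated on genes outside chromosome 9. Transcripts of named genes and pseudogenes were aligned to all others with blastn 2.17.0. A copy counted as near-identical at 98% or more over at least 200 bases. Of 191 distinct named genes, 28 had such a copy, 5 overlapped another gene on the same strand and 33 on the opposite strand, and their values are uncertain.

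The tests were run on simulated counts for the 17473 genes with 200 changed. In the CKO against WT comparison under CRE, edgeR recovered 4% of 1.5-fold, 58.5% of 2-fold and 88.5% of 4-fold changes. For the interaction it recovered 0.5%, 33% and 79.5%. Under PBS these shares were 8%, 64% and 85.5%, and false calls at 2-fold were 6.6% of calls, against 18.4% for DESeq2. For the CRE effect they were 3.5%, 61% and 90.5% in WT and 8%, 59% and 88% in CKO. The real CRE contrasts called 9959 and 6830 genes, far more than the 200 changed here. Adjustment is stricter with fewer changed genes, so these shares do not give the recovery in the real CRE contrasts. No libraries of a group agreed within sampling noise, with chi-square per degree of freedom from 4.72 to 89.6 between replicates. The labels do not say that replicates are separate animals, so the p-values measure only the spread between these libraries. By Y-linked counts CKO_PBS, WT_CRE and CKO_CRE each held both sexes, hence more than 1 mouse. For WT_PBS and for libraries of the same sex this stays open.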

Results

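Whole-lung poly(A) RNA was sequenced from mice of 2 genotypes given PBS or CRE. The series title names Clara cells, allergic airway inflammation, the airway barrier and interstitial macrophages. Clara cells, also called club cells, are secretory cells of the airway lining, and Cc10, the product of *Scgb1a1*, is their marker. Cc10-Cre mice (WT) were set against Cc10-Cre mice with floxed *Rhoa* (CKO), in which Cre would remove the small GTPase gene *Rhoa* from Cc10-expressing cells. Each of the 4 groups held 3 libraries, with totals of 16250674 to 21559210 counts.

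CRE treatment was the main axis of variation. Principal component 1 held 64.4% of the variance of log2 CPM, with scores of -61.7 ± 2.08 in WT_PBS, -58.0 ± 9.77 in CKO_PBS, 78.4 ± 6.57 in WT_CRE and 41.3 ± 37.3 in CKO_CRE (SD, n = 3). The CKO_CRE libraries were far apart, at 10.1, 82.6 and 31.2. Component 2 held 8.3% and separated the genotypes, at 20.7 ± 0.73 and 22.3 ± 10.8 in WT against -13.0 ± 0.89 and -29.9 ± 3.65 in CKO. Immunoglobulin genes took 0.0581% ± 0.00595 of counts in WT_PBS, 0.0606% ± 0.0264 in CKO_PBS, 0.549% ± 0.113 in WT_CRE and 0.364% ± 0.222 in CKO_CRE. By Y-linked counts, all 3 WT_PBS libraries were male, CKO_PBS held 1 female, and WT_CRE and CKO_CRE held 2 females each. Sex therefore differed along the CRE comparisons and between the PBS groups.

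**Figure D1:**
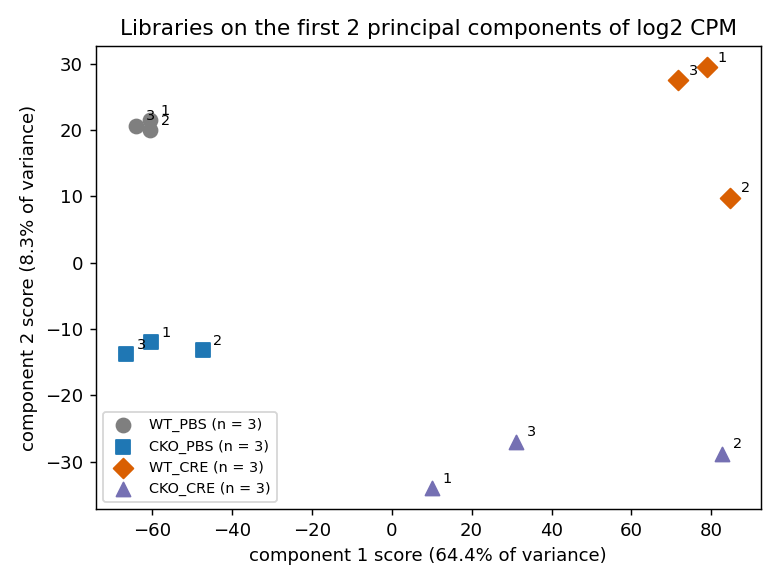
Scores of the 12 libraries on principal components 1 and 2 of log2 CPM, with replicate numbers beside the points. WT_CRE and 1 CKO_CRE library lie between 71.6 and 84.7 on component 1, and the other CKO_CRE libraries at 10.1 and 31.2.

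The targeted gene *Rhoa* (ENSMUSG00000007815, chromosome 9, 108306129 to 108337934) was measured at 488, 471 and 485 CPM in WT_PBS and 469, 398 and 481 CPM in CKO_PBS. It was at 523, 531 and 521 CPM in WT_CRE and 465, 544 and 495 CPM in CKO_CRE. The CKO minus WT difference was -0.10 ± 0.10 on the log2 scale under PBS (adjusted p = 1) and -0.07 ± 0.10 under CRE (adjusted p = 0.728). Averaged over treatments it was -5.6%, with a lower 95% bound of -14.1%. No fall in whole lung was called, and a fall larger than that bound lies outside the range of the estimate. Cc10-expressing cells are a minority of whole lung, so these levels do not check the labels. *Rhoa* has a near-identical pseudogene and overlaps *Tcta* on the opposite strand, so its counts carry that uncertainty.

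In WT lungs, CRE raised type 2 immune genes, and several rose from near the detection floor. The eosinophil-attracting chemokine *Ccl24* rose from 0.368 ± 0.255 to 566 ± 134 CPM (log2 10.61 ± 0.66, adjusted p = 1.31e-06). *Ccl11*, another eosinophil chemokine, rose from 5.15 ± 1.33 to 161 ± 18.6 CPM (log2 4.96 ± 0.23, adjusted p = 2.23e-07). The cytokine *Il13* rose from 0.126 ± 0.0438 to 12.9 ± 3.16 CPM (adjusted p = 8.58e-06), and *Il5* from 0.0701 ± 0.0269 to 1.16 ± 0.561 CPM (adjusted p = 0.000535). *Il5* overlaps *Gm12214* on the opposite strand. *Il4* changed less, from 2.12 ± 0.608 to 3.93 ± 1.05 CPM (log2 0.90 ± 0.32, adjusted p = 0.033), and its call was lost without WT_PBS replicate 1 (adjusted p = 0.123) or 2 (0.0883) or WT_CRE replicate 1 (0.0746) or 2 (0.129). Of 14 tested type 2 cytokine and chemokine genes, 13 rose over all genes and 13 adjusted over the list alone (camera adjusted p = 8.03e-12; adjusted p = 0.114 with an estimated correlation).

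Macrophage genes rose strongly. Of 16 genes of alternative macrophage activation, 15 rose by either adjustment (camera adjusted p = 1.31e-24; adjusted p = 0.0674 with an estimated correlation). Among them *Arg1*, which encodes arginase, rose from 2.80 ± 0.285 to 1338 ± 299 CPM (log2 8.89 ± 0.86), *Chil4* from 0.592 ± 0.527 to 960 ± 294 CPM, and *Chil3*, a chitinase-like protein, from 865 ± 104 to 9474 ± 890 CPM (log2 3.45 ± 0.16, adjusted p = 2.23e-07). Of 19 interstitial macrophage genes, 15 rose and 2 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 1.56e-11; adjusted p = 0.114 with an estimated correlation). The complement gene *C1qa* rose from 63.2 ± 10.9 to 554 ± 30.8 CPM (log2 3.13 ± 0.29) and *Trem2* by log2 3.94 ± 0.43, while *Lyve1* fell by 1.26 on the log2 scale. The 18 alveolar macrophage genes moved both ways, 8 up and 7 down by either adjustment, with a rise of *Ctsk* (log2 2.57) and falls of *Fabp1* (log2 -5.95 ± 0.57) and *Cidec* (log2 -3.64 ± 0.46). Its camera test pointed up without passing (adjusted p = 0.104), while its median was -0.04 and its mean -0.18, and the test passed without CKO_CRE replicate 2 (adjusted p = 0.0255).

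Mucus, plasma cell and proliferation genes also rose. All 17 tested mucus and goblet cell genes rose by either adjustment (camera adjusted p = 7.68e-17; adjusted p = 0.0958 with an estimated correlation), with the mucin *Muc5ac* going from 6.55 ± 2.12 to 67.2 ± 1.95 CPM (log2 3.35 ± 0.34, adjusted p = 2.51e-05). The immunoglobulin heavy chain gene *Ighg1* rose from 1.13 ± 0.503 to 654 ± 246 CPM, and 15 of 16 B and plasma cell genes rose by either adjustment (camera adjusted p = 3.66e-07; adjusted p = 0.234 with an estimated correlation). All 18 cell cycle genes rose by either adjustment, among them *Birc5* (log2 3.02 ± 0.31) and *Cdk1* (camera adjusted p = 2.73e-18; adjusted p = 0.165 with an estimated correlation). The mast cell protease gene *Mcpt1* had 0 counts in WT_PBS and reached 4.41 ± 2.65 CPM, at least 27.4-fold higher. The mast cell and basophil list was not called (camera adjusted p = 0.248), as 4 of 11 genes rose and 2 fell by either adjustment. Among those that fell was *Cpa3* (log2 -1.25 ± 0.29, adjusted p = 0.00324). Of 18 interferon response genes 12 rose by either adjustment (camera adjusted p = 0.0106; adjusted p = 0.567 with an estimated correlation), and the list's call was lost without CKO_CRE replicate 2 (adjusted p = 0.0529) or with sex as a covariate (0.0695).

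Genes of several epithelial cell types fell as a share of whole-lung counts. These values do not tell lower expression per cell from a smaller share of such cells in the lung. Of 20 club cell genes, 16 fell and 1 rose by either adjustment (camera adjusted p = 7.97e-11; adjusted p = 0.165 with an estimated correlation). *Scgb3a2*, a secretoglobin of club cells, fell from 2318 ± 87.7 to 190 ± 11.4 CPM (log2 -3.61 ± 0.30), *Pon1* from 81.4 ± 9.89 to 2.67 ± 0.308 CPM (log2 -4.92 ± 0.26), and *Scgb1a1* from 35.5 ± 3.57 to 8.30 ± 1.63 CPM (log2 -2.10 ± 0.36, adjusted p = 0.000532), while *Reg3g* rose (log2 2.70 ± 0.49). Of 15 ciliated cell genes 13 fell, 14 adjusted over the list alone (camera adjusted p = 0.000309; adjusted p = 0.368 with an estimated correlation). Of 12 type 1 alveolar cell genes 11 fell and 1 rose by either adjustment, with *Rtkn2* and *Akap5* at log2 -2.28 and -2.30 (camera adjusted p = 3.83e-08; adjusted p = 0.165 with an estimated correlation). Of 20 tight junction genes 12 fell and 3 rose, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.00632; adjusted p = 0.28 with an estimated correlation). *Cldn18* fell from 855 ± 69.3 to 424 ± 39.2 CPM (log2 -1.01 ± 0.12, adjusted p = 4.79e-05) and *Tjp1* by 1.20 on the log2 scale, whereas *Cldn4* rose (log2 3.09 ± 0.58) and *Tjp3*, which overlaps *Apba3* on the opposite strand, rose (log2 0.80 ± 0.14). Markers of cardiac muscle, a tissue other than the airway and alveolar lining, moved with these lists, and 9 of 11 fell by either adjustment (median -1.32; camera adjusted p = 0.000534; adjusted p = 0.349 with an estimated correlation).

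Altogether 9959 of 17473 tested genes changed with CRE in WT lungs, 5003 higher and 4956 lower, and 3982 of them by at least 2-fold. Of the 36 lists, 22 were called, 15 higher and 7 lower, and none of these held with an estimated correlation (adjusted p from 0.0674 to 0.567). Since all WT_PBS libraries were male and WT_CRE held 2 females, the count with sex as a covariate, chosen after seeing the data, was 7934. *Rhoa* did not pass (log2 0.12 ± 0.10, adjusted p = 0.288).

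**Figure D2:**
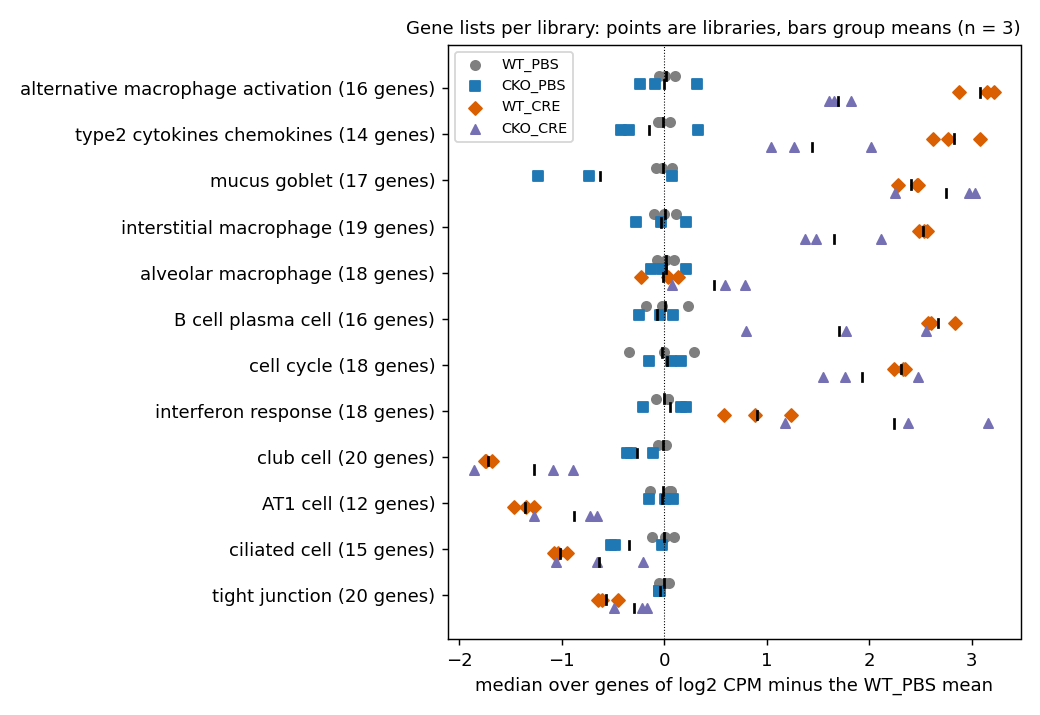
Median over the genes of each list of log2 CPM minus the mean of WT_PBS, per library (points), with group means as bars (n = 3). Tight junction, type 1 alveolar, ciliated and club cell lists lie below 0 in all 6 CRE libraries. For the cell cycle list the CKO_CRE libraries run from 1.55 to 2.48 and the WT_CRE libraries from 2.24 to 2.35.

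In CKO lungs, CRE also raised mucus, chemokine and macrophage genes. *Muc5ac* rose from 3.24 ± 1.99 to 134 ± 27.4 CPM (log2 5.36 ± 0.38, adjusted p = 7.47e-06), *Ccl24* from 0.163 ± 0.0586 to 117 ± 86.5 CPM (adjusted p = 8.4e-06), *Chil3* from 1041 ± 133 to 8916 ± 1075 CPM (log2 3.10 ± 0.16, adjusted p = 8.17e-07) and *Ccl11* from 4.51 ± 1.38 to 89.7 ± 13.5 CPM (log2 4.31 ± 0.23). *Il13* rose from 0.0616 ± 0.107 to 3.07 ± 1.08 CPM (adjusted p = 0.000145) and *Il5* from 0.0486 ± 0.00279 to 0.535 ± 0.363 CPM (adjusted p = 0.00598; 0.0964 with limma-voom). *Il4*, at 1.70 ± 0.577 and 1.91 ± 0.451 CPM, did not pass (log2 0.17 ± 0.34, adjusted p = 0.721). All 17 mucus genes rose by either adjustment (camera adjusted p = 3.37e-28; adjusted p = 0.00778 with an estimated correlation), and 15 of 16 alternative activation genes rose and 1 fell by either adjustment (camera adjusted p = 6.67e-27; adjusted p = 0.0152 with an estimated correlation). These were the 2 lists of this contrast whose call held. Of 14 type 2 genes 11 rose by either adjustment (camera adjusted p = 1.38e-10; adjusted p = 0.102 with an estimated correlation).

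All 18 interferon response genes rose in CKO lungs by either adjustment, led by *Cxcl10* (log2 3.63 ± 0.50) and the ubiquitin-like modifier *Isg15* (log2 3.21 ± 0.42) (camera adjusted p = 9.63e-12; adjusted p = 0.268 with an estimated correlation). *Cxcl10* overlaps *Art3* on the opposite strand. Of 19 interstitial macrophage genes 16 rose and 1 fell, or 16 and 2 adjusted over the list alone, with *C1qa* at log2 2.79 ± 0.28 (adjusted p = 7.66e-05; camera adjusted p = 3.33e-14; adjusted p = 0.0632 with an estimated correlation). The 18 cell cycle genes all rose by either adjustment (camera adjusted p = 7.87e-22; adjusted p = 0.137 with an estimated correlation). Of 20 club cell genes 13 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 3.84e-07; adjusted p = 0.268 with an estimated correlation), with *Pon1* at log2 -2.91 ± 0.24, *Scgb3a2* at -2.06 ± 0.28 and *Scgb1a1* at -1.56 ± 0.35 (adjusted p = 0.00533). Of 15 ciliated cell genes 1, *Tppp3*, fell by either adjustment, and the list did not pass (camera adjusted p = 0.179), but it passed without CKO_CRE replicate 1 (0.0225). Of 20 tight junction genes 4 fell and 2 rose by either adjustment (camera adjusted p = 0.231), and *Cldn18* fell from 851 ± 42.7 to 583 ± 74.5 CPM (log2 -0.55 ± 0.12, adjusted p = 0.00389). Of 11 cardiac muscle genes 7 fell, 9 adjusted over the list alone (camera adjusted p = 0.00167; adjusted p = 0.35 with an estimated correlation).

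In all, 6830 genes changed with CRE in CKO lungs, 3595 higher and 3235 lower, and 2105 by at least 2-fold. Of the 36 lists 21 were called, 16 higher and 5 lower, and the calls lost had adjusted p from 0.0632 to 0.535 with an estimated correlation. Fitting only the CKO libraries called 3812 genes, and sex as a covariate, chosen after seeing the data, left 5798. *Rhoa* did not pass (log2 0.16 ± 0.10, adjusted p = 0.21).

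The CRE responses of the genotypes overlapped. Of the called genes, 3220 were higher in both genotypes, where 1029.3 would be shared by independent lists, 2922 were lower in both (917.6), and 8 went opposite ways. Across genes, which are not independent replicates, log2 fold changes had a Pearson correlation of 0.84 and a Spearman correlation of 0.844, and the contrasts share no library. Among genes called in WT, 88.8% changed less in CKO. Choosing genes by their call in WT favours a smaller value in CKO by itself, and in 20 simulations with no genotype effect, which leave out differences in response between libraries, the share was 58.1% on average and at most 59.0%.

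Under PBS, 19 genes differed between the genotypes, and most lay on chromosome 9, which carries *Rhoa*. *Nxpe4* fell from 28.2 ± 3.02 to 2.67 ± 0.673 CPM (log2 -3.40 ± 0.30, adjusted p = 0.000254), and *Gclc*, which encodes the catalytic subunit for glutathione synthesis, from 240 ± 11.2 to 102 ± 1.22 CPM (log2 -1.23 ± 0.12, adjusted p = 0.000572). *Nxpe2* (log2 -4.61 ± 0.46) and *Hykk* (log2 -1.73 ± 0.18) also fell. The ribosomal protein gene *Rpl29* (chromosome 9, 106429454 to 106431568), named after its values were seen, fell from 219 ± 18.9 to 36.8 ± 3.55 CPM (log2 -2.57 ± 0.15, adjusted p = 6.3e-06). It has near-identical pseudogenes, so this value is uncertain. Away from chromosome 9, the heme synthesis gene *Alad* (chromosome 4, 62509169 to 62519918) rose from 31.0 ± 0.948 to 62.8 ± 3.66 CPM (log2 1.02 ± 0.07, adjusted p = 6.13e-05). *Nnmt* (log2 -1.58) lost its call without any 1 of the WT_PBS or CKO_PBS libraries (adjusted p from 0.0537 to 0.0906), and *Pxylp1* (log2 -1.24) without WT_PBS replicate 2 (0.1) or 3 (0.0675) or CKO_PBS replicate 3 (0.0744). *Fanca* (chromosome 8, log2 -1.33, adjusted p = 0.0376), which overlaps *Zfp276* on the opposite strand, lost its call without any 1 of the WT_PBS or WT_CRE libraries or CKO_PBS replicate 1 or 3 (0.0525 to 0.267), or among genes outside chromosome 9 alone (0.0912).

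Of the 19 genes, 11 (57.9%) were on chromosome 9, against 978 of 17473 tested genes (5.6%; one-sided Fisher's exact p = 7.98e-10, chosen after the positions were seen). Of the fixed set under PBS, *Il13*, *Il4*, *Il5*, *Ccl11*, *Chil3*, *C1qa*, *Cldn18* and *Scgb1a1* had an adjusted p of 1, and *Muc5ac* differed by log2 -1.02 ± 0.38 without passing (adjusted p = 0.726). The counts were 7 higher and 12 lower, with 930 genes at an unadjusted p below 0.05. The count was 12 without WT_PBS replicate 2, WT_PBS replicate 3 or CKO_PBS replicate 3, 33 without CKO_PBS replicate 2 and 53 without CKO_CRE replicate 2. The higher genes numbered 4 without any 1 of the WT_PBS libraries or CKO_PBS replicate 3, 15 without CKO_PBS replicate 1, 13 without CKO_PBS replicate 2, 12 without WT_CRE replicate 2 and 20 without CKO_CRE replicate 2. The lower genes numbered 20 without CKO_PBS replicate 2 and 33 without CKO_CRE replicate 2.

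Among the lists under PBS, the neutrophil list was higher in CKO (median log2 1.17; camera adjusted p = 2.92e-06; adjusted p = 0.629 with an estimated correlation), with 0 of 15 members called over all genes and 9 adjusted over the list alone. Its median against WT_PBS was 0.959, 1.272 and 0.245 in CKO_PBS replicates 1, 2 and 3, and up to 0.226 in single WT_PBS libraries. Lower lists were mucus (camera adjusted p = 6.61e-06, median -0.09), club cell (6.61e-06, median -0.32) and ciliated cell (7.33e-06, median -0.33), each with an adjusted p = 0.629 with an estimated correlation. They had 0 members called over all genes, and 2, 1 and 0 adjusted over the list alone. CKO_PBS replicate 2, the only female PBS library, did not share the fall of mucus and ciliated cell genes. Its list medians (log2 against WT_PBS) were 0.08 for mucus (others -0.732 and -1.231, WT_PBS -0.078 to 0.075) and -0.026 for ciliated cells (others -0.517 and -0.475, WT_PBS -0.116 to 0.096). For club cells it was -0.11 (others -0.361 and -0.323, WT_PBS -0.057 to 0.022). The cell lists of smooth muscle (camera adjusted p = 0.00246), cardiac muscle (0.0115), fibroblast and matrix (0.0242) and type 2 alveolar cells (0.0445) were higher, with adjusted p = 0.629, 0.777, 0.629 and 0.905 with an estimated correlation. Smooth muscle lost its call without WT_PBS replicate 2 (0.0502) or CKO_PBS replicate 2 (0.181), cardiac muscle without WT_PBS replicate 2 (0.352) or CKO_PBS replicate 1 (0.138) or 3 (0.116), and fibroblast and matrix without WT_PBS replicate 1 (0.0536) or 2 (0.102) or CKO_PBS replicate 3 (0.245). Type 2 alveolar cells lost theirs without WT_PBS replicate 2 (0.0946) or 3 (0.233), CKO_PBS replicate 1 (0.0787) or 3 (0.181), WT_CRE replicate 1 (0.0557) or 2 (0.0573) or CKO_CRE replicate 3 (0.0538).

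**Figure D3:**
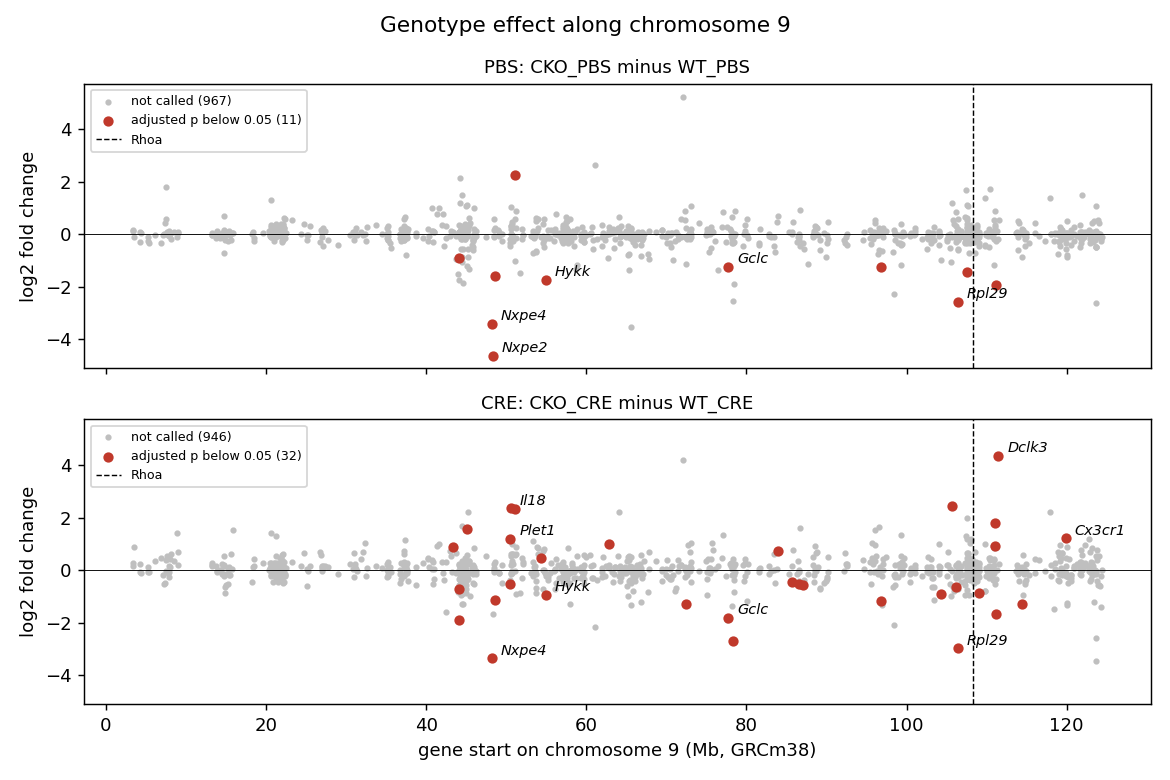
Log2 fold change of CKO over WT for the 978 tested genes of chromosome 9 by gene start (Mb, GRCm38), under PBS (upper) and CRE (lower), with genes at an adjusted p below 0.05 in red and *Rhoa* as a dashed line. There are 11 such genes under PBS and 32 under CRE.

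Under CRE, the scavenger receptor gene *Cd163* of macrophages was lower in CKO, at 59.1 ± 3.72 against 147 ± 6.01 CPM (log2 -1.31 ± 0.14, adjusted p = 0.000693), as was *Tdo2*, which encodes a tryptophan-degrading enzyme, at 6.06 ± 1.49 against 26.7 ± 2.84 CPM (log2 -2.14 ± 0.21, adjusted p = 0.000549). *Fpr1*, a formyl peptide receptor gene, was higher, at 8.74 ± 3.21 against 1.16 ± 0.619 CPM (log2 2.88 ± 0.34, adjusted p = 0.00202). *Dclk3*, which lies on chromosome 9 as *Rhoa* does, was higher, at 2.08 ± 1.02 against 0.0963 ± 0.0380 CPM (log2 4.36 ± 0.61, adjusted p = 0.00735). Its WT_CRE mean lay below the floor of 3 counts per library (0.168 CPM on average), so its fold is uncertain. *Cd163*, *Tdo2*, *Fpr1* and *Dclk3* kept their calls without any 1 library. *Ccl24* was lower in CKO, at 117 ± 86.5 against 566 ± 134 CPM (log2 -2.27 ± 0.40, adjusted p = 0.0234), but lost its call without WT_CRE replicate 1 (0.103) or 2 (0.0626) or CKO_CRE replicate 3 (0.0849). *Il13* was lower, at 3.07 ± 1.08 against 12.9 ± 3.16 CPM (log2 -2.07 ± 0.38, adjusted p = 0.028), but lost its call without any 1 of the WT_PBS or WT_CRE libraries or CKO_CRE replicate 1 or 3 (0.0516 to 0.11). *Nos2*, the inducible nitric oxide synthase gene, was lower (log2 -2.69 ± 0.50, adjusted p = 0.0317), and lost its call without any 1 of the WT_PBS or WT_CRE libraries or CKO_PBS or CKO_CRE replicate 3 (0.052 to 0.133). Fitting only the CRE libraries ended the calls of *Fpr1* (0.0926), *Dclk3* (0.0755), *Ccl24* (0.222), *Il13* (0.0823) and *Nos2* (0.258), while *Cd163* and *Tdo2* still passed.

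Of 18 alveolar macrophage genes, 4 were higher in CKO under CRE over all genes, and 7 higher and 3 lower adjusted over the list alone. The median of the list was 0.05 (log2), and its test pointed up (camera adjusted p = 0.00727; adjusted p = 0.354 with an estimated correlation) but did not pass without CKO_CRE replicate 2 (0.215). The list median against WT_PBS was 0.077 in that library, within the WT_CRE libraries (-0.222 to 0.138), and 0.791 and 0.59 in CKO_CRE replicates 1 and 3. The 4 included *Krt79*, at 50.8 ± 24.7 against 5.18 ± 3.83 CPM (log2 3.29 ± 0.46, adjusted p = 0.0077; 0.0589 without WT_CRE replicate 1), and *Fabp1* (log2 3.80 ± 0.63, adjusted p = 0.018; 0.103 without WT_CRE replicate 1 and 0.0953 without replicate 3). *Fabp1* was at 1.40 ± 0.552 against 0.0935 ± 0.0612 CPM, so its WT_CRE mean lay below the floor of 3 counts and its fold is uncertain. Of 19 interstitial macrophage genes, 2 were higher and 2 lower, or 2 and 3 adjusted over the list alone. The test of this list pointed down (camera adjusted p = 0.00727; adjusted p = 0.468 with an estimated correlation) but did not pass without CKO_CRE replicate 1 (0.311). *Cx3cr1*, a chemokine receptor gene on chromosome 9, was higher (log2 1.22 ± 0.19, adjusted p = 0.0125; 0.0599 without WT_CRE replicate 1 and 0.0531 without CKO_CRE replicate 3), and the transcription factor gene *Maf* was lower (log2 -0.50 ± 0.08, adjusted p = 0.018; 0.0558, 0.0585 and 0.0813 without WT_CRE replicates 1, 2 and 3). Both overlap a predicted gene on the opposite strand. The interferon-induced gene *Ifit1* was higher, at 150 ± 88.9 against 38.1 ± 5.84 CPM (log2 1.98 ± 0.37, adjusted p = 0.032), and lost its call without any 1 of the WT_PBS or WT_CRE libraries or CKO_CRE replicate 3 (0.0564 to 0.157). The collagen gene *Col1a2* was lower (log2 -0.53 ± 0.10, adjusted p = 0.0322), and lost its call without any 1 of the WT_PBS or WT_CRE libraries or CKO_PBS or CKO_CRE replicate 3 (0.0535 to 0.167). Fitting only the CRE libraries ended the calls of *Krt79* (0.151), *Fabp1* (0.0926), *Cx3cr1* (0.0889), *Maf* (0.201), *Ifit1* (0.219) and *Col1a2* (0.308). Of the largest rises, those of *Tpm3-rs7*, *Trim34b* and *Selenbp2* are of genes with a near-identical copy, so their values are uncertain and are not described further.

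**Figure D4:**
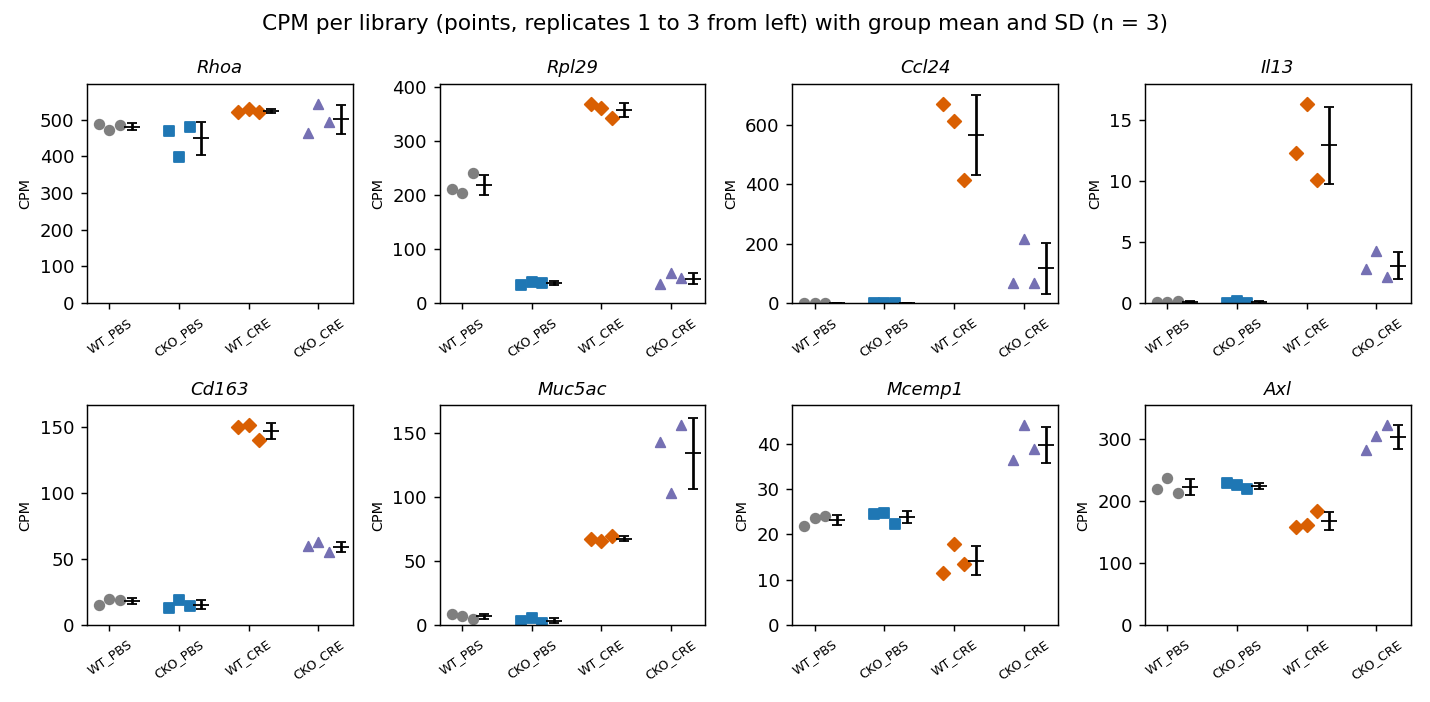
CPM of 8 genes in each library (points, replicates 1 to 3 from the left) with the group mean and SD (n = 3). *Cd163*, *Ccl24* and *Il13* are lower in every CKO_CRE library than in every WT_CRE library, and *Rpl29* is lower in every CKO library than in every WT library.

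*Muc5ac* (log2 0.99 ± 0.30, adjusted p = 0.134), *Ccl11* (-0.85 ± 0.19, 0.0603), *Cldn18* (0.46 ± 0.12, 0.0854), *Il4* (-1.04 ± 0.33, 0.149), *Il5* (-1.11 ± 0.51, 0.273), *C1qa* (-0.47 ± 0.26, 0.346), *Scgb1a1* (0.57 ± 0.37, 0.402) and *Chil3* (-0.09 ± 0.15, 0.761) did not pass. Without CKO_CRE replicate 2, *Muc5ac* (adjusted p = 0.00907), *Ccl11* (0.00242), *Cldn18* (0.0048), *C1qa* (0.00749) and *Scgb1a1* (0.0355) passed, and *Ccl11* passed also without CKO_PBS replicate 2 (0.039). DESeq2 called *Ccl11* (0.00205) and *Cldn18* (0.00543), limma-voom these (1.74e-05 and 8.82e-05), *Muc5ac* (6.01e-05) and *Il5* (0.0021), and the fit with no low-count filter *Ccl11* (0.00289), *Cldn18* (0.0442) and *Muc5ac* (0.0142). In all 160 genes differed between genotypes under CRE, 96 higher and 64 lower in CKO, and 32 of them lay on chromosome 9 (one-sided Fisher's exact p = 2.45e-10, chosen after the positions were seen). The count rested on single libraries. It was 5112 without CKO_CRE replicate 2, 61 without CKO_CRE replicate 3, 38, 90 and 63 without WT_CRE replicates 1, 2 and 3, 79, 80 and 74 without WT_PBS replicates 1, 2 and 3, and 93 without CKO_PBS replicate 3. Without CKO_CRE replicate 1, 151 genes were higher and 51 lower. Fitting only the CRE libraries called 29 genes, while the fit with no low-count filter called 691 and DESeq2 799, with 13.2% false calls at 2-fold in simulated counts against 5.6% for edgeR. Limma-voom, which weighted CKO_CRE replicate 2 at 0.122 and CKO_CRE replicate 3 at 3.47, called 7645.

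Of the 36 lists, 18 were called under CRE, 8 higher and 10 lower in CKO, and none held with an estimated correlation (adjusted p from 0.235 to 0.552). The test of the type 2 list pointed down in CKO (camera adjusted p = 1.74e-10; adjusted p = 0.235 with an estimated correlation), with 3 of 14 members lower over all genes and 9 adjusted over the list alone. That of alternative macrophage activation also pointed down (camera adjusted p = 7.09e-12; adjusted p = 0.235 with an estimated correlation), with 2 of 16 and 11 members. That of the interferon list pointed up (camera adjusted p = 2.69e-12; adjusted p = 0.354 with an estimated correlation), with 3 of 18 members higher over all genes and 13 adjusted over the list alone. The list median against WT_PBS was 1.177 in CKO_CRE replicate 1, within the WT_CRE libraries (0.586 to 1.233), and 2.377 and 3.154 in replicates 2 and 3. The tests of the type 1 alveolar (camera adjusted p = 4.36e-08) and tight junction (0.000904) lists pointed up, both with adjusted p = 0.354 with an estimated correlation. Of these, 1 of 12 and 0 of 20 were called over all genes, and 11 and 4 adjusted over the list alone. The test of the club cell list pointed up by camera with its preset correlation (adjusted p = 6.29e-05) and did not pass with an estimated one (adjusted p = 0.43), and 0 of 20 members were called by edgeR over all genes and 9 were higher adjusted over the list alone. In these 3 epithelial lists CKO_CRE replicate 2 did not share the shift. Its list median (log2 against WT_PBS) was -1.265 for type 1 alveolar genes, where the other CKO_CRE libraries were at -0.724 and -0.655 and WT_CRE at -1.461 to -1.272. For tight junction genes it was -0.49, against -0.172 and -0.216 and WT_CRE at -0.645 to -0.448. For club cell genes it was -1.854, below every WT_CRE library (-1.742 to -1.68), against -0.886 and -1.081. The cardiac muscle list moved with these epithelial lists (median 0.87; camera adjusted p = 7.32e-06; adjusted p = 0.354 with an estimated correlation), with 0 of 11 members called by edgeR over all genes and 8 higher adjusted over the list alone.

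The difference between the CRE responses of the genotypes was called for 8 genes. *Rbpj*, which encodes the DNA-binding partner of Notch, went from 89.6 ± 1.58 to 135 ± 6.42 CPM in WT and from 67.9 ± 9.32 to 43.7 ± 3.01 CPM in CKO (interaction log2 -1.22 ± 0.14, adjusted p = 0.0244). Its near-identical pseudogene *Rbpj-ps3* was called higher in CKO under CRE (log2 4.73, adjusted p = 0.011), so the value of *Rbpj* is uncertain. *Axl*, a receptor tyrosine kinase gene, went from 223 ± 13.1 to 168 ± 14.0 CPM in WT and from 225 ± 4.93 to 303 ± 19.5 CPM in CKO (interaction log2 0.84 ± 0.13, adjusted p = 0.0458). *Mcemp1*, a mast cell and myeloid membrane protein gene, went from 23.2 ± 1.11 to 14.2 ± 3.28 CPM in WT and from 23.8 ± 1.31 to 39.7 ± 3.92 CPM in CKO (interaction log2 1.45 ± 0.20, adjusted p = 0.0458). *Fpr1*, *Klra2*, *Slc16a11* and *Plet1* also had positive interactions and *Tdo2* a negative one (adjusted p = 0.0458 each). With sex as a covariate the calls of *Axl*, *Klra2* and *Tdo2* (0.0614 each), *Slc16a11* (0.0691), *Fpr1* and *Plet1* (0.0983 each) ended. With the replicate number as a block in edgeR, all 8 calls ended. *Plet1*, which lies on chromosome 9, overlaps *Plet1os* on the opposite strand.

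The interaction of *Muc5ac* (log2 2.01 ± 0.48, adjusted p = 0.244), *Cldn18* (0.46 ± 0.16, 0.412), *Ccl11* (-0.65 ± 0.30, 0.483), *Chil3* (-0.36 ± 0.21, 0.549), *Il4* (-0.73 ± 0.47, 0.582), *Scgb1a1* (0.54 ± 0.50, 0.685), *Il13* (-1.19 ± 1.23, 0.715), *C1qa* (-0.34 ± 0.37, 0.732) and *Il5* (-0.62 ± 1.37, 0.874) did not pass. Without CKO_CRE replicate 2, *Muc5ac* (adjusted p = 0.00978) and *Cldn18* (0.0342) passed. *Muc5ac* was also called by DESeq2 (0.0107), limma-voom (0.0026) and the fit with no low-count filter (0.00819), and *Cldn18* by limma-voom (0.00346). At an unadjusted p below 0.05 there were 1801 genes, and the called count depended on each library. With edgeR it was 0 without WT_PBS replicate 1 or 2, CKO_PBS replicate 1 or 2, WT_CRE replicate 1 or 3 or CKO_CRE replicate 3, with 1233 to 1982 genes at an unadjusted p below 0.05. It was 1 without WT_PBS or CKO_PBS replicate 3, 4 without WT_CRE replicate 2, 24 without CKO_CRE replicate 1 and 2660 without CKO_CRE replicate 2. DESeq2, with 16.5% false calls at 2-fold in simulated counts against 4.3% for edgeR, called 119, limma-voom with the same library weights 4371, the fit with no low-count filter 81, and sex as a covariate, chosen after seeing the data, left 2.

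Among the 9959 genes called with CRE in WT, 87.2% had the opposite sign in CKO minus WT under CRE. These contrasts share the WT_CRE libraries, so chance gives a negative relation. In 20 simulations with no genotype effect the share was 55.9% on average and at most 56.9%, but these leave out differences in response between libraries. The 9 other splits of the same 6 CRE libraries, which do not follow genotype, gave 59.4 to 93.7%, and 3 of them lay above the real value. The covariance across genes was -0.39 against -0.0534 in the simulations, a difference of -0.337. Of these genes, 8 were called for the interaction, 101 were called under CRE with the opposite sign and 12 with the same sign. The share was 77.3% without CKO_CRE replicate 1, 91.7% without replicate 2 and 82% without replicate 3.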

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

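The tests of chromosome 9, of pseudogenes, of single CKO_CRE libraries and of mislabelling were chosen after the result was seen. The genes and lists given here stood out because their CRE response differed between WT and CKO in the test of that difference (CKO response minus WT response, log2). The genes were *Rbpj* (-1.22), *Tdo2* (-2.34), *Mcemp1* (1.45), *Klra2* (1.44), *Fpr1* (2.99), *Slc16a11* (1.60), *Plet1* (1.35) and *Axl* (0.84). With 1 library left out their highest adjusted p was 0.161 for *Rbpj*, 0.221 for *Tdo2*, *Mcemp1* and *Klra2*, and 0.229 for *Fpr1*, *Slc16a11*, *Plet1* and *Axl*.

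Lists with a lower response in CKO, by camera and with their median difference, were type 2 cytokines and chemokines (-0.69), alternative macrophage activation (-0.62), interstitial macrophages (-0.34), eosinophils (-0.88), neutrophils (-1.26), T cells (-0.69), B and plasma cells (-0.67), acute inflammation (-0.42), fibroblasts and matrix (-0.45), smooth muscle (-0.23), cell cycle (-0.37) and unfolded protein response (-0.36). For neutrophils the value went mostly with a higher CKO level under PBS (median CKO minus WT 1.17). Under CRE the genotypes were not called apart for that list (median -0.18, camera adjusted p = 0.11). Lists with a positive difference, CKO response minus WT response, were interferon response (1.21), alveolar macrophages (0.17), club cells (0.67), ciliated cells (0.80), type 1 alveolar cells (0.53), endothelium (0.23), cardiac muscle (0.41), skeletal muscle and adipose (0.97) and tight junctions (0.29). The medians of the club, ciliated, type 1 alveolar, endothelium, cardiac muscle and tight junction lists fell with CRE in both genotypes. Their positive values mark a smaller fall in CKO. For the club and ciliated lists this went partly with a lower CKO level under PBS (median CKO minus WT -0.32 and -0.33). Under CRE these medians were 0.63 and 0.34. None of these 21 calls held with an estimated correlation (adjusted p from 0.263 to 0.556). Leaving out CKO_CRE replicate 1 ended the calls of interstitial macrophages (adjusted p = 0.212), endothelium (0.242) and cardiac muscle (0.0613). Leaving out CKO_CRE replicate 2 ended those of alveolar macrophages (0.16), smooth muscle (0.471) and skeletal muscle and adipose (0.0982), and leaving out CKO_CRE replicate 3 those of endothelium (0.0562) and cardiac muscle (0.123). Without CKO_PBS replicate 2, interstitial macrophages (0.0547), endothelium (0.0992), smooth muscle (0.139) and cardiac muscle (0.111) lost theirs. Without WT_PBS replicate 1 interstitial macrophages (0.0695) and cardiac muscle (0.0846) did, without WT_PBS replicate 2 smooth muscle (0.076), without WT_PBS replicate 3 cardiac muscle (0.0624), and without WT_CRE replicate 2 eosinophils (0.0784). With sex as a covariate endothelium (0.0764) lost its call.

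Single libraries also moved the median difference of several of these lists by more than 1.5 times. Without CKO_CRE replicate 1 it was -0.069 for interstitial macrophages, -0.454 for T cells, -0.372 for B and plasma cells, 0.484 for ciliated cells, 0.091 for endothelium and -0.188 for cell cycle. Without CKO_CRE replicate 2 it was -0.625 for interstitial macrophages, -1.13 for B and plasma cells, -0.915 for acute inflammation, 0.359 for endothelium and -0.723 for cell cycle. Without CKO_CRE replicate 3 it was 0.257 for alveolar macrophages, -0.265 for acute inflammation, 0.243 for cardiac muscle and -0.222 for cell cycle. Without CKO_PBS replicate 2 it was -0.143 for interstitial macrophages, -0.409 for T cells, -0.243 for acute inflammation, 0.999 for club cells, -0.135 for smooth muscle, 0.213 for cardiac muscle and -0.239 for unfolded protein response. Acute inflammation was at -0.662 without CKO_PBS replicate 1, -0.204 without WT_PBS replicate 3 and -0.244 without WT_CRE replicate 2. Alveolar macrophages were at 0.11 without WT_PBS replicate 2, 0.29 without WT_CRE replicate 2 and 0.098 without WT_CRE replicate 3. Cell cycle was at -0.225 without WT_PBS replicate 1, cardiac muscle at 0.646 without WT_CRE replicate 1 and eosinophils at -0.45 without WT_CRE replicate 2.

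Genes called between genotypes gathered on chromosome 9, with 57.9% of the 19 calls under PBS and 32 of the 160 under CRE there, against 5.6% of tested genes. The 34 genes called there under either treatment lay from 43.3 to 120.1 Mb, a stretch that holds *Rhoa* and most of the tested span of 3.3 to 124.5 Mb. Reads shared between genes and pseudogenes may contribute. Of 11 called pseudogenes on other chromosomes, 5 (45.5%) had their closest coding transcript on chromosome 9, against 5.1% of other pseudogenes (one-sided Fisher's exact p = 0.000209). All 11 were higher in CKO under CRE. Of the 5 parent genes on chromosome 9, *Rpl29* (log2 -2.97), *Tma7* (-0.88) and *Cyb5r4* (-0.56) were called lower there, and *Eef1a1* and *Ddx6* were not called. Whether such sharing differs between the genotypes was not tested. DNA from another strain carried along with the floxed allele is another candidate explanation, but the gathering prompted it and so does not test it, and no sequence variants were examined. Loss of *Rhoa* in Cc10-expressing cells was not tested either, and all of these stay open.

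The CRE response looked smaller in CKO. For 87.2% of the genes called in WT, the CKO minus WT difference under CRE had the opposite sign to the WT response. Only 8 genes were called for CRE in opposite directions in the genotypes. A mislabelled CKO_CRE library is argued against, since at least 14 of 19 genes called under PBS lay on the CKO side in every CKO_CRE library, and so is sex, since WT_CRE and CKO_CRE held 2 females each and the share with sex as a covariate was 89.1%. The share was at most 56.9% in simulations of the shared WT_CRE libraries and at least 77.3% without any 1 CKO_CRE library, but the simulations are too low a bar, because they leave out differences in response between libraries and the 9 other splits of the 6 CRE libraries gave 59.4 to 93.7%. With the real split, 4 of the 10 reached 87.2%, and 10 splits are too few to test chance. Chance in the shared libraries and a single library therefore stay open, as do uneven exposure to CRE and a smaller response through loss of *Rhoa*, which were not tested.

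Other splits of the libraries were fitted for each count. For CRE in WT the real split called 9959 genes and the highest other 0, for CRE in CKO 6830 and 2, and for genotype under PBS 19 and 0. For each, 1 of the 10 splits, the real one, reached the real count, and 10 splits are too few for a test. In the other splits with a count of 0 by edgeR, 175 to 370 genes for CRE in WT, 377 to 2355 for CRE in CKO, 257 to 475 for genotype under PBS and 294 to 3187 under CRE had an unadjusted p below 0.05, and other tools were not run on them. For genotype under CRE the real split called 160 and another 3708, and 2 of the 10 reached 160, which are again too few splits for a test. That other split set WT_CRE replicates 1 and 2 and CKO_CRE replicate 2 against the rest. These lay at 78.9, 84.7 and 82.6 on principal component 1, and WT_CRE replicate 3 and CKO_CRE replicates 1 and 3 at 71.6, 10.1 and 31.2. The split thus follows the order along that component. It follows genotype only in part and does not follow sex. For the interaction, 7 of 100 splits drawn from 200 gave 8 or more genes and the highest other gave 1124, so chance cannot be excluded.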

How the results depend on the processing

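The sex covariate and the fits outside chromosome 9 were chosen after seeing the data, and where no reason is given the cause was not tested. Gene values were counted as kept if they stayed on their side of the threshold, with the same direction where either fit called them. Kept were 2293 of 2372 for CRE in WT, 2016 of 2103 for CRE in CKO and 349 of 369 for genotype under PBS. For genotype under CRE 498 of 694 were kept, and for the interaction 243 of 339. Genes called in neither fit counted as kept whatever their direction. Of the named genes, 9 of 19 were called for genotype under PBS, 26 of 35 under CRE and 8 of 18 for the interaction. Calls were lost in 20, 178 and 89 values of these contrasts, all of called genes. The CKO minus WT difference of *Rhoa*, averaged over treatments, stayed within -0.04 to -0.11 (log2). The genotype and interaction counts depend most on the settings, and edgeR recovered 4% of simulated 1.5-fold changes under CRE, so many effects of that size would be missed there. Depth was not varied.

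At 2-fold or more, CRE in WT gave 2107 higher and 1875 lower, CRE in CKO 1441 and 664, genotype under CRE 62 and 37, and the overlap of CRE responses between genotypes 1810, because the threshold is stricter. Fitting only the groups compared gave 2133 higher and 1679 lower for CRE in CKO, 30 and 44 for genotype under PBS and 19 and 10 under CRE. DESeq2 gave 53 and 55 for genotype under PBS, 520 and 279 under CRE and 77 and 42 for the interaction. Limma-voom gave 54 and 92, 4011 and 3634, and 2527 and 1844. No low-count filter gave 53 and 36, 488 and 203, and 60 and 21. Outside chromosome 9, where fewer genes are tested, genotype gave 4 and 0 under PBS by edgeR (805 at an unadjusted p below 0.05) and 63 and 33 under CRE. The sex covariate left 1 and 1 for the interaction.

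Leaving out each library in turn gave, higher then lower, 4241 to 5424 and 4210 to 5445 for CRE in WT, 2602 to 4119 and 2165 to 3659 for CRE in CKO, 4 to 20 and 8 to 33 for genotype under PBS, 22 to 2829 and 16 to 2283 under CRE, and 0 to 1564 and 0 to 1096 for the interaction, the top values of the genotype and interaction counts without CKO_CRE replicate 2. The overlap of CRE responses between genotypes was 4375 to 7004 and the opposite share 77.3 to 91.7%. Under PBS without CKO_PBS replicate 2, the medians of alternative macrophage activation (-0.234, adjusted p = 0.0118; range -0.234 to 0.129) and immediate early genes (-0.208, adjusted p = 0.000542; range -0.208 to 0.466) reversed. The cause was not tested.

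With the replicate number as a block the calls were 9919, 6999, 17 and 151 for the CRE and genotype contrasts, and 0 for the interaction by edgeR, both higher and lower (2009 at an unadjusted p below 0.05). Deviations from the group means correlated at -0.033 to 0.176 between libraries with the same number (median 0.023), over 0.1 in 4 of 18 pairs. Other pairs correlated at -0.247 to 0.176 (median -0.014), over 0.1 in 2 of 36. Of 12 libraries, 8 correlated best with their own number. A factor shared by libraries of the same number is therefore not excluded.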

Other observations

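Other epithelial and stromal genes moved with CRE in ways not described above. Surfactant genes did not move together. *Sftpd*, a surfactant collectin, rose from 1075 ± 123 to 2677 ± 262 CPM in WT (log2 1.32 ± 0.16, adjusted p = 7.45e-05) and from 1124 ± 88.6 to 2246 ± 523 CPM in CKO (log2 1.00 ± 0.16, adjusted p = 0.000966), while *Sftpb* fell in CKO from 4169 ± 66.6 to 2521 ± 278 CPM (log2 -0.73 ± 0.11, adjusted p = 0.000627). In WT, *Sftpb* was likewise lower with CRE, at 2243 ± 101 CPM against 3786 ± 182 CPM with PBS. *Timp1*, a metalloproteinase inhibitor, rose from 10.3 ± 1.26 to 385 ± 145 CPM in WT (log2 5.23 ± 0.59). The endothelial receptor gene *Tek* fell in WT (log2 -1.56 ± 0.20, adjusted p = 9.73e-05), and 10 of 13 endothelial genes fell in WT by either adjustment (camera adjusted p = 0.000534; adjusted p = 0.354 with an estimated correlation).

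Genes of the RhoA and ROCK pathway moved both ways with CRE in WT, 8 of 26 up and 12 down by either adjustment (camera adjusted p = 0.248). The actin-binding gene *Pfn1* rose (log2 1.29 ± 0.18) and the non-muscle myosin gene *Myh10* fell (log2 -1.79 ± 0.23). Between genotypes this list was not called under PBS (camera adjusted p = 0.957, test higher with median -0.02 and mean -0.0049) or CRE (0.172; 0.0351 with no low-count filter). In both cases 0 of 26 members were called by edgeR over all genes and 0 adjusted over the list alone.

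*Scgb1a1*, the Cc10 gene, was low for a club cell marker gene, at 35.5 ± 3.57 CPM in WT_PBS where *Scgb3a2* was at 2318 ± 87.7 CPM. *Rbpj-ps3*, a pseudogene near-identical to *Rbpj*, was at 0.455, 0.453 and 0.648 CPM in WT_PBS, 0.413, 3.51 and 4.37 CPM in CKO_PBS, 0.631, 0.109 and 0.321 CPM in WT_CRE and 8.47, 8.65 and 10.8 CPM in CKO_CRE.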
